A study of Mus musculus with 48 samples.

How the data were processed

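RNA of mouse aorta was measured on 48 arrays in 3 knockout models, Eln, Efemp2 and Lox. Per the labels, aortas were snap frozen, RNA of 8 aortas was pooled for each array, RNA was extracted with RNeasy Plus Mini, and 5 ng was amplified with NuGEN Ovation Pico WTA and labelled with biotin. The Eln and Efemp2 mice were on C57BL/6 and the Lox mice on B6 albino. The deposited values are log2 summaries per probe set that the authors made with RMA in Affymetrix Expression Console. The versions of both, the array name and the genome build are not given in the labels.

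The values point to more than 1 normalization run. The lowest values of arrays coincided exactly in 15 of 28 array pairs of the Eln E17.5 arrays, 14 of 28 of Efemp2 E17.5, 15 of 28 of Lox E17.5 and 45 of 120 of the Eln and Efemp2 P1 arrays together, and in 0 of 28 of Lox P1, while 1 array pair shared such a value across sets. Array medians ran from 4.35 to 4.55, 4.36 to 4.47, 3.71 to 3.82, 4.52 to 4.89 and 4.85 to 5.35 in these sets. No label states this. Each KO and the WT of the same model, location and stage lay within 1 set, except that no shared values place the Lox P1 arrays in 1 run. There the medians were 4.85 to 5.19 in KO and 5.21 to 5.35 in WT. Stages did not lie within 1 set, so a difference between the stages in WT cannot be told apart from a difference between the sets.

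The table held 41345 probe sets. Of these, 23521 carried 1 gene symbol, 1814 several and 16010 none, and the 22180 distinct single symbols were taken as genes. Of the single-symbol probe sets, 23328 were matched to RefSeq by gene ID, and 0 symbols differed. A gene was tested when at least 1 group mean reached 4.94, the median over all single-symbol probe sets, which left 15330 genes. Probe sets with several symbols or none were tested in a fit of their own for the closing section. No array was left out.

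A linear model with a mean for each of the 24 groups of 2 arrays was fitted to all 48 arrays with limma 3.58.1 in R 4.3.3, with 24 residual degrees of freedom and moderated variances from eBayes. KO less WT was taken in each of the 12 model, location and stage pairs and as the mean of the 4 pairs of each model. The differences of these effects between models, between DA and AA and between P1 and E17.5 were tested as contrasts of the same fit, and so were DA less AA and P1 less E17.5 in the WT arrays. P values were adjusted by the Benjamini-Hochberg method over the tested genes of each contrast, with a threshold of 0.05. Genes past it in the same direction in the mean contrast of each model were counted as changed in all 3 models. Where the median difference of all tested genes went beyond 0.1, gene values are given less that median. List medians of single pairs are always given less the median of all tested genes in the pair.

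Before the data were examined, 32 gene lists of pathways, cell types and functions were written down, with 499 genes, of which 451 had a probe set of their own and 426 were tested. Each list was tested in the 3 mean KO contrasts and both WT contrasts with camera, which sets a list against the other genes, at its preset correlation of 0.01. Its p values were adjusted over the lists of a contrast, and the test was repeated with a correlation estimated for each list. List members were also adjusted over the list alone.

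The genes named in the text followed a rule written before the data were examined. It named the deleted genes in every KO contrast. For each mean KO contrast it named the 10 rising and 10 falling genes with the largest difference among those past the threshold with the same sign in all 4 pairs, and for the WT contrasts the same with the sign in all 6 pairs. It named up to 3 and 3 for single pairs, up to 5 and 5 for differences of effects, 10 and 10 for all 3 models by the smallest of the 3 differences, and up to 4 members per list or all of a list of at most 6. Predicted genes, olfactory and vomeronasal receptors and small RNA families were skipped by set patterns of their names, so a small RNA gene with another name could remain.

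The alternatives were no filter, cyclic loess over all arrays, only the arrays of the comparison, eBayes with trend and robust variances, a block for the replicate number as a fixed or a random term (statmod 1.5.0), an estimated correlation in camera, and leaving out each array in turn. The array background as a covariate and a fit without 4 arrays of raised background were added after the data were seen. For the covariate, background was measured as the median of 1394 olfactory and vomeronasal receptor genes. The 4 arrays were those of the Eln and Efemp2 P1 arrays with the highest medians of probe sets without a gene name, 4.35 to 4.37 against at most 4.14, while by receptor medians 3 of them, at 3.11, 3.23 and 3.23, were near an array that was kept, at 3.11, and 1 stood apart at 3.53. To see whether other groupings of the arrays call as many genes, 100 splits were drawn per result with seed 20240.

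The fit was tested on simulated data with 15330 genes, of which 200 were changed. Changes of 1 on the log2 scale were recovered for 98.0% of genes in a mean KO contrast, 39.0% in a single pair, 80.0% between models, 41.0% between locations and 36.0% between stages, with 10, 0, 3, 7 and 6 false calls. Changes of 0.5 were recovered for 60.0%, 3.0%, 20.0%, 5.0% and 2.0%. Without any change 0 genes were called in a mean KO contrast, the only kind for which this was simulated. A list raised by 0.3, the collagen list, passed camera at adjusted p = 3.7e-22, or adjusted p = 1.6e-08 with an estimated correlation, and 0 of 31 other lists did. The genes were simulated as independent, while the correlation estimated for the collagen list in the data was 0.32. The simulation therefore cannot show how either form of camera behaves on correlated genes. The number of arrays limits precision most in single pairs and in differences of effects by location or stage. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Sex of the pooled animals was not used here.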

Results

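Gene expression was measured on 48 arrays of mouse aorta from 3 knockout models of elastic fibre formation. The Eln model lacks elastin, the core protein of the elastic fibre. The Efemp2 model lacks fibulin-4, a matrix protein that brings lysyl oxidase to elastin. The Lox model lacks lysyl oxidase, the enzyme that cross-links elastin and collagen. Knockout (KO) and wild-type (WT) aortas of each model were taken as ascending aorta (AA) and descending aorta (DA), on embryonic day 17.5 (E17.5) and postnatal day 1 (P1). This gave 24 groups of 2 arrays, and each array held RNA of 8 pooled aortas. Each KO was compared with the WT of its own model, and the number of arrays limits the precision. All values are log2 array signals and all differences are KO less WT unless another order is given. Errors are standard errors from limma, and a pair is the KO and WT of 1 location and stage of a model. In the averaged contrasts the 4 pairs of a model hold 8 arrays per genotype. The median array value ran from 3.71 to 5.35, and replicate arrays correlated across genes at a median r of 0.970 (lowest 0.875), where genes are not independent replicates. Among the Eln and Efemp2 arrays at P1, 4 had a raised signal on probe sets without a gene name, with medians of 4.35 to 4.37. These were both Eln WT DA arrays and replicate 2 of Efemp2 WT AA and of Efemp2 WT DA, and the other 12 P1 arrays of these models had medians of at most 4.14. The Lox WT arrays at P1, of another normalization set, had medians of 4.67 to 4.74. The 4 arrays are called the 4 high-background arrays in what follows.

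The deleted genes were examined first in every group. Eln (probe set 17453454) averaged 4.46 to 5.44 in the 4 Eln KO groups and 10.43 to 11.90 in the Eln WT groups, and it fell by 6.12 ± 0.22 on the log2 scale (adjusted p = 2.5e-19, lower in 4 of 4 pairs). Lox (probe set 17354367) averaged 7.10 to 8.59 in the Lox KO groups and 9.56 to 11.45 in the Lox WT groups, and it fell by 2.66 ± 0.16 (adjusted p = 1.5e-12, 4 of 4 pairs). Replicate 1 of the Lox KO arrays at E17.5 kept more Lox signal than replicate 2, at 7.99 against 6.56 in AA and 7.93 against 6.26 in DA. Without replicate 2 of the KO the fall of Lox no longer passed the test in either E17.5 pair. In DA at E17.5 it also did not pass in a fit of the Lox arrays alone, where 0 genes were lower. No probe set carried the name Efemp2 in the annotation used here, so the deletion in that model could not be checked. In Eln KO, Lox rose by 0.58 ± 0.16 (adjusted p = 0.042, 4 of 4 pairs), a call that ended in 18 of 24 settings, among them the fit without the 4 high-background arrays and leaving out any 1 of 13 arrays. Lox differed by 0.49 ± 0.16 in Efemp2 KO (adjusted p = 0.092, 4 of 4 pairs) and did not pass the test. Eln differed by 0.31 ± 0.22 in Efemp2 KO and by 0.23 ± 0.22 in Lox KO, and neither difference passed. A pair of WT arrays had less Eln than their replicates, at 9.20 against 11.65 in Eln WT DA P1 and 9.69 against 11.70 in Efemp2 WT AA E17.5.

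**Figure D1:**
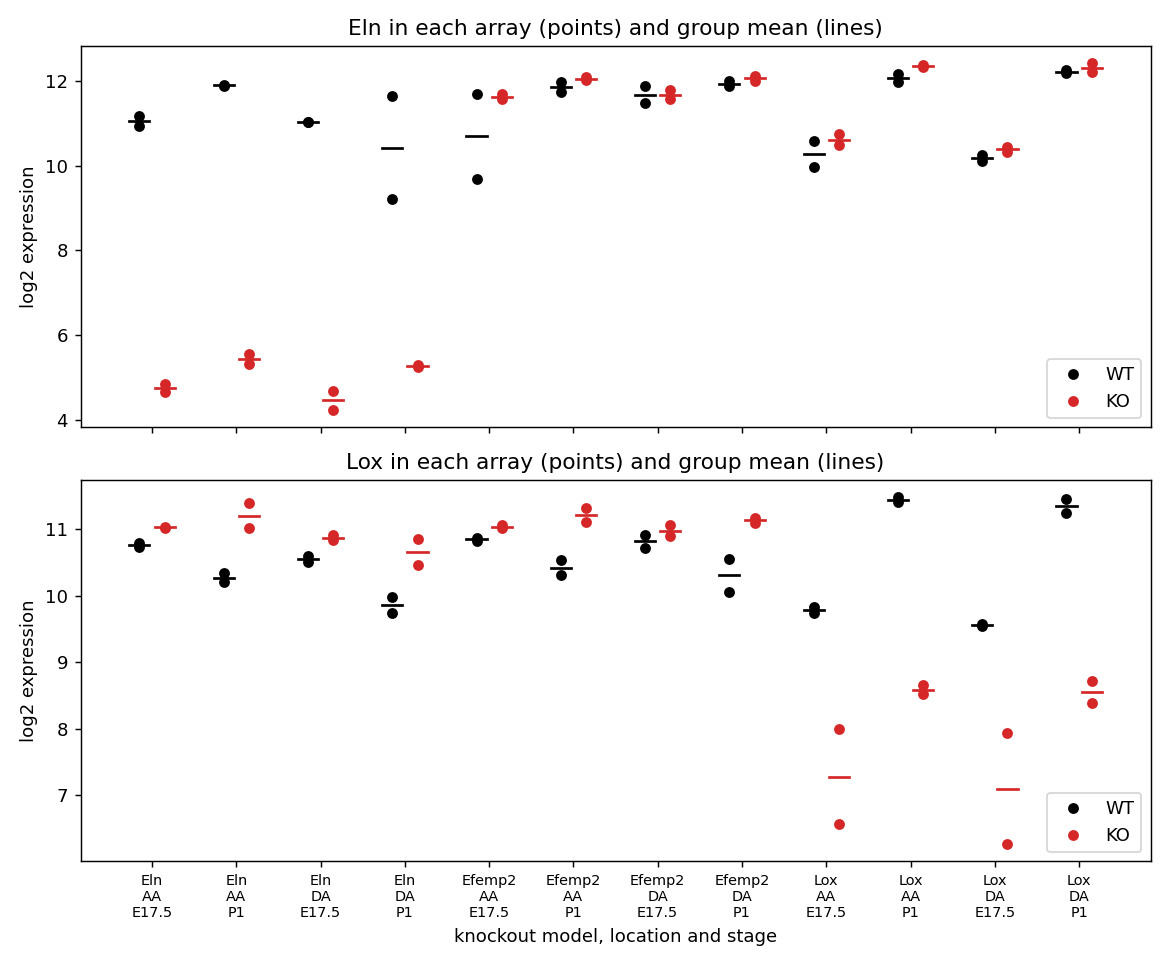
Log2 array signal of Eln and Lox in each array (points) with the group means of 2 arrays (lines) for the 12 combinations of model, location and stage, WT in black and KO in red. Eln stands at group means of 4.46 to 5.44 in Eln KO against 10.43 or more in Eln WT, and Lox at 7.10 to 8.59 in Lox KO against 9.56 or more in Lox WT.

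The comparison of the models asked which genes change in every elastic fibre defect. Genes of matrix and matrix adhesion were among the largest shared rises. Col8a1, a short-chain collagen of vessel walls, rose by 2.32 ± 0.18 in Eln KO, 2.94 ± 0.18 in Efemp2 KO and 2.54 ± 0.18 in Lox KO. Igfbp2, which binds insulin-like growth factors, rose by 2.02, 2.32 and 1.48 in the same order (SE 0.17 each). Thbs1, the matricellular protein thrombospondin 1, rose by 0.96, 2.06 and 1.41 (SE 0.17 each), and Ccn2, a matricellular growth factor cofactor, by 1.11, 1.14 and 0.83 (SE 0.14 each). The fibril collagen gene Col11a1 rose by 1.07, 1.41 and 1.09 (SE 0.13 each), and Itga11, a subunit of a collagen receptor, by 1.30, 1.20 and 0.98 (SE 0.13 each). The other 4 of the 10 rises with the largest smallest difference were Itgbl1, Ier3, Tnnc1 and Adamts8, between 0.80 and 1.69. The shared falls included Clca3a2 (-1.59, -1.04 and -1.27), Pi15, which encodes a peptidase inhibitor (-1.40, -0.82 and -1.05), and Slc26a7, an anion transporter gene (-0.84, -0.98 and -0.78). Butyrylcholinesterase (Bche), a subunit of a GABA receptor (Gabrb2) and a neuropeptide Y receptor (Npy1r) fell in all 3 models as well, and so did Ndst3, Alpl and Stxbp6. All 19 had adjusted p values of 0.0482 or less in each model and the same sign in 4 of 4 pairs, apart from Npy1r and Alpl in Eln KO (3 of 4). Over 24 other settings per model, Stxbp6 lost its call in 12, 21 and 19 in Eln, Efemp2 and Lox KO, Npy1r in 13 in Eln KO and Tnnc1 in 7 in Lox KO. Alpl in Eln KO and Bche in Efemp2 KO lost it in 1 each.

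In the limma fit, 44 of 15330 tested genes passed an adjusted p of 0.05 in the same direction in all 3 models, 34 higher and 10 lower. Independent sets of these sizes would share 0.0743 and 0.00555 genes. Eln KO and Efemp2 KO shared 116 higher genes (13.2 for independent sets) and 18 lower genes (0.552). Eln KO and Lox KO shared 41 and 21, and Efemp2 KO and Lox KO shared 59 and 21. Between 0 and 2 genes per pair of models passed in opposite directions. The models share the variance estimate of each gene, so their calls are not independent. The 4 high-background arrays are all WT arrays at P1 of the Eln and Efemp2 models. With the array background as a covariate 136 genes were higher in Eln KO and 241 in Efemp2 KO. The overlaps of pairs of models were not counted again under other settings. Across genes, the averaged differences of Efemp2 KO and Lox KO correlated at r = 0.509, those of Eln KO and Efemp2 KO at 0.373 and those of Eln KO and Lox KO at 0.351, where genes are not independent replicates.

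**Figure D2:**
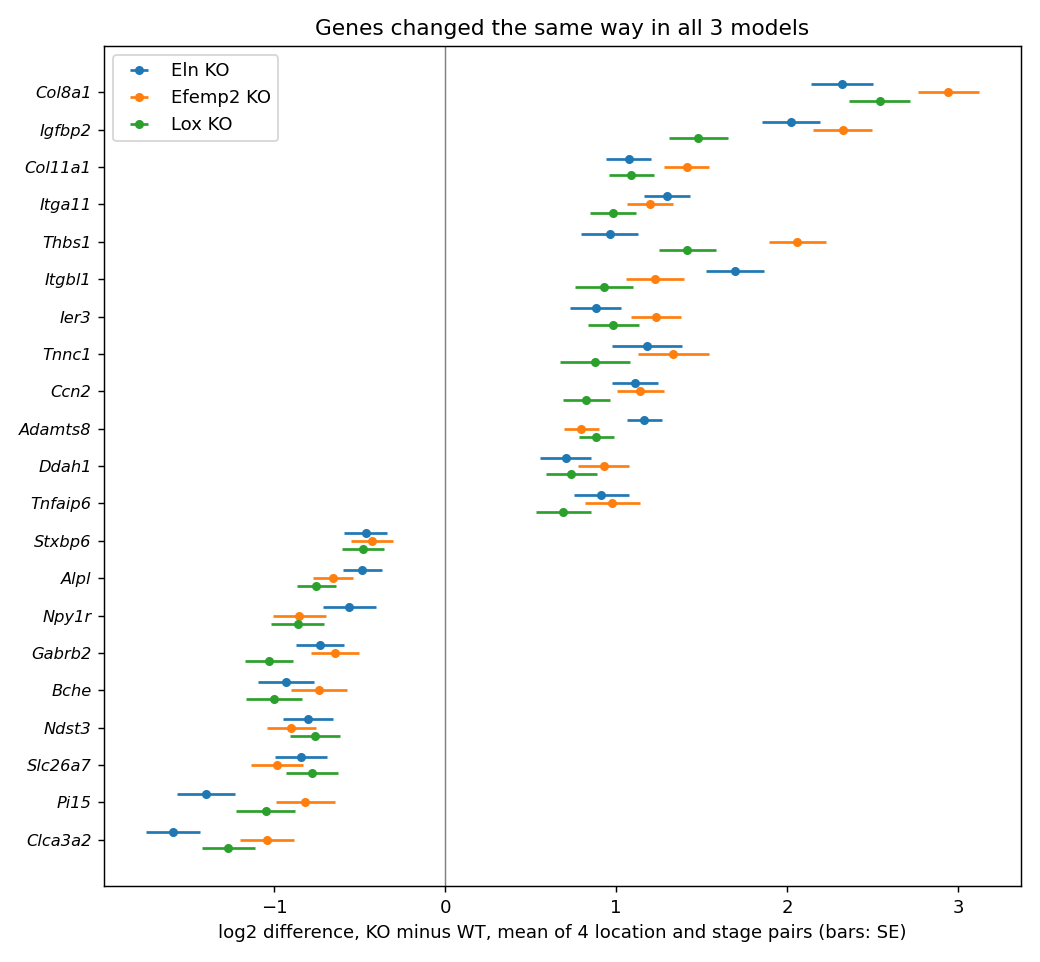
Log2 difference, KO less WT, averaged over the 4 location and stage pairs (points) with its standard error (bars) in Eln (blue), Efemp2 (orange) and Lox KO (green), for 12 genes higher and 9 genes lower in all 3 models. Col8a1 has the largest difference, at 2.32, 2.94 and 2.54, and the 9 lower genes lie between -0.43 and -1.59.

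In Eln KO aorta the changed genes were of several functions, and no list passed with an estimated correlation. Besides Col8a1, Igfbp2, Itga11 and Itgbl1 (1.69 ± 0.17), the largest rises were Gna14, a G protein subunit gene (1.51 ± 0.15), Chad, a cartilage matrix protein gene (1.49 ± 0.26), Crabp2, a retinoic acid binding protein gene (1.49 ± 0.17), Moxd1 (1.41 ± 0.15), Stmn2, a neuronal growth gene (1.31 ± 0.26), and Tenm3 (1.21 ± 0.14). Apart from Eln, the largest falls were Clca3a2, Pi15, the chemokine gene Cxcl13 (-1.05 ± 0.16), the fatty acid receptor gene Cd36 (-1.04 ± 0.27) and the small RNA gene AF357399 (-1.04 ± 0.30), followed by Btbd35f12, Bche, Enpp3 and Slc26a7 between -0.84 and -0.94. Each of these 20 genes had the same sign in 4 of 4 pairs, and their adjusted p values were at most 0.0455. Stmn2, Enpp3, Btbd35f12, AF357399 and Cd36 lost their calls under at least 1 alternative setting.

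Of 21 tested genes of the elastic fibre list, 9 rose and 1, Eln itself, fell in Eln KO (12 and 2 adjusted over the list alone). Ltbp2, a microfibril protein gene, rose by 1.18, and Emilin1 (0.63) and Fbn2 (0.73) rose as well but passed no longer without the 4 high-background arrays. The list's median was 0.42 and its mean 0.03, since Eln is a member, and camera gave adjusted p = 1.3e-04, or adjusted p = 0.31 with an estimated correlation. Of 22 collagen genes, 7 rose (9 rose and 1 fell adjusted over the list alone), among them Col8a1, Col11a1, P4ha3 (0.88) and Plod2 (0.85), the last pair being collagen hydroxylases. That list had a median of 0.22 with adjusted p = 2.6e-08, or adjusted p = 0.199 with an estimated correlation. Of 14 TGF-beta signalling genes 5 rose (5 rose and 2 fell adjusted over the list alone), led by Pmepa1, an induced inhibitor of the pathway (0.99), with adjusted p = 0.00199, or adjusted p = 0.216 with an estimated correlation. Of 14 YAP targets 3 rose (5 adjusted over the list alone), Ccn2, Crim1 (0.45) and Lats2 (0.45), of which Ccn2 alone kept its call under all alternatives, with adjusted p = 1.3e-04, or adjusted p = 0.113 with an estimated correlation. Of 17 smooth muscle contractile genes 3 rose (6 adjusted over the list alone), among them Smtn (0.60) and Cald1 (0.46), at a median of 0.28 and adjusted p = 3.6e-05, or adjusted p = 0.244 with an estimated correlation. Of 10 glucocorticoid response genes 3 rose (8 adjusted over the list alone), among them the metallothionein gene Mt2 (0.90), at a median of 0.40 and adjusted p = 1.7e-06, or adjusted p = 0.113 with an estimated correlation. Mt2, Smtn and Cald1 lost their calls with the array background as a covariate. Of 13 basement membrane genes 2 rose (9 adjusted over the list alone), among them Nid2 (0.62), with adjusted p = 8.9e-05, or adjusted p = 0.272 with an estimated correlation. Of 18 immediate early genes 1, Ier3, rose (4 adjusted over the list alone), with adjusted p = 0.00342, or adjusted p = 0.354 with an estimated correlation. At E17.5 the medians in AA and DA were 0.029 and 0.049 for elastic fibre, 0.024 and -0.010 for collagen and -0.041 and 0.038 for basement membrane genes. At P1 they were 0.45 and 0.67, 0.22 and 0.57, and 0.34 and 0.77, and those of the glucocorticoid response were 0.70 and 0.82, against -0.003 and -0.14 at E17.5. These list medians are given less the median shift of all tested genes in each pair, which was 0.017 in AA P1 and 0.27 in DA P1. Of 24 other settings, Crim1 lost its call in 19, Lats2 in 14, Emilin1 and Smtn in 3, Cald1 and Mt2 in 2 and Fbn2 in 1. Both WT arrays of the DA P1 pair had high background, and the difference of the lists between stages was not tested.

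Some markers of other cell types differed in Eln KO. Of 12 brown fat genes 4 fell (8 adjusted over the list alone), among them Cd36, the fat cell regulator Pparg (-0.78) and Fabp4 (-0.49), at a median of -0.51 and adjusted p = 2.0e-09, or adjusted p = 0.113 with an estimated correlation. Of 13 fibroblast genes 3 fell and 1 rose (4 and 2 adjusted over the list alone), with Dpt (-0.73), Lum (-0.48) and Dcn (-0.39), all genes of small matrix proteins, among the falls and adjusted p = 1.4e-04, or adjusted p = 0.216 with an estimated correlation. Of 9 neuron and Schwann cell genes 2, Stmn2 and Prph (0.96), rose (6 adjusted over the list alone), at adjusted p = 9.3e-04, or adjusted p = 0.244 with an estimated correlation. Less the median shift of all tested genes in each pair, that list's median was 0.95 in AA and 1.04 in DA at E17.5 and 0.11 and 0.41 at P1. In the cartilage list Chad, Hapln1 (1.08) and Acan (0.51) rose, and the list did not pass (adjusted p = 0.136). Of 24 other settings, Acan lost its call in 15, Cd36 in 9, Pparg in 6, Fabp4 in 5, Prph in 3, and Dcn and Stmn2 in 1. Emcn, an endothelial surface gene, fell by 1.04 on average while 15 of the 17 endothelial genes did not pass in either direction. The Emcn effect was higher in DA than in AA, by 1.61 less the median shift. The endothelial list median at P1, less the shift, was -0.43 in AA and 0.52 in DA, where both WT arrays had high background. The interferon response (median -0.10, adjusted p = 0.021) and heart muscle lists (median -0.22, adjusted p = 0.027) were lower by camera, with adjusted p = 0.425 and adjusted p = 0.593 with an estimated correlation. In limma 0 of 9 interferon response genes passed. Of 14 heart muscle genes 1 rose and 0 fell, against the direction of the list. The remaining 19 of the 32 lists had adjusted p values from 0.073 to 0.89, and none of the 13 lists that passed did so with an estimated correlation.

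For the mean Eln KO contrast limma gave 504 genes, 421 higher and 83 lower. The count was 383 after cyclic loess (243 higher, 140 lower), 218 with the array background as a covariate (136 and 82), 248 without the 4 high-background arrays (145 and 103), and 331 to 872 with 1 array left out.

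In Efemp2 KO aorta, the acute phase genes Saa3 and Serpina3n rose by 2.55 ± 0.29 and 2.51 ± 0.30. The haem-degrading enzyme gene Hmox1 rose by 1.93 ± 0.21, the neutrophil and monocyte gene S100a8 by 1.85 ± 0.29, and the prostaglandin synthase gene Ptgs2 by 1.72 ± 0.23. Cstdc4 (1.81 ± 0.36) and Stfa2l1 (adjusted p = 2.2e-04), both of the cystatin family, rose as well, with Col8a1, Igfbp2 and Thbs1 completing the 10 largest rises. The falls were smaller. Clca3a2, Slc26a7, Ndst3, Npy1r and Pi15 were joined by Glb1l2 (-0.78 ± 0.17), Chil5, Gkn3, Bche and Amigo2. Each of these 20 genes had the same sign in 4 of 4 pairs, with adjusted p values of at most 0.0234. Amigo2, Gkn3, Chil5 and Bche lost their calls in a fit of the Efemp2 arrays alone. Of the 20 genes, 18 kept theirs without any 1 array.

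Of 15 macrophage genes 9 rose in Efemp2 KO and none fell (14 adjusted over the list alone), among them the integrin gene Itgam (1.33), lysozyme (Lyz2, 1.22) and the lysosomal gene Cd68 (1.08). The list's median was 0.65, and it passed in camera at adjusted p = 7.3e-16, or adjusted p = 0.0134 with an estimated correlation. Less the median shift of all tested genes in each pair, its median was 1.16 in AA and 0.30 in DA at E17.5, and 0.72 and 0.30 at P1. Of the blood lists, the platelet genes had a median of 0.33 over the 4 pairs, with 1 gene higher, Pf4 (0.53), 3 adjusted over the list alone, and adjusted p = 0.00216, or adjusted p = 0.125 with an estimated correlation. The erythroid genes had a median of 0.30 and did not pass (adjusted p = 0.0531). In the AA E17.5 pair the platelet and erythroid medians, less the median shift of all tested genes, were 1.00 and 0.62. The thymocyte and lymphocyte list (median 0.31, 1 of 10 higher, 2 higher and 1 lower adjusted over the list alone) passed at adjusted p = 0.0304, or adjusted p = 0.393 with an estimated correlation. Of 17 endothelial genes 4 fell and 1 rose (9 and 1 adjusted over the list alone), with the junction genes Cldn5 (-0.56) and Cdh5 (-0.52) lower and Flt1 (0.79) higher. That list passed downward at adjusted p = 4.0e-06, or adjusted p = 0.0692 with an estimated correlation. Of 24 other settings, Pf4 lost its call in 16, Cdh5 in 2 and Cldn5 in 1.

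Of 22 collagen genes 8 rose in Efemp2 KO (9 adjusted over the list alone), among them Col12a1 (1.06) and P4ha1 (0.71), at a median of 0.29 and adjusted p = 1.4e-10, or adjusted p = 0.0557 with an estimated correlation. Of 10 glucocorticoid response genes 5 rose (7 adjusted over the list alone), with the metallothionein genes Mt1 (0.70) and Mt2 and the growth factor feedback gene Errfi1 (0.83) among them, and adjusted p = 2.2e-09, or adjusted p = 0.0134 with an estimated correlation. Of 12 hypoxia and glycolysis genes 4 rose (7 adjusted over the list alone), among them the glucose transporter gene Slc2a1 (0.72) and the glycolytic gene Pgk1 (0.67), with adjusted p = 1.0e-05, or adjusted p = 0.0134 with an estimated correlation. Of 14 unfolded protein and amino acid stress genes 3 rose (4 adjusted over the list alone), Asns (0.45), Calr (0.43) and Hspa5 (0.30), with adjusted p = 2.4e-04, or adjusted p = 0.0104 with an estimated correlation. These 3 lists and the macrophage list were the 4 that passed both ways. Of 18 immediate early genes 4 rose (11 adjusted over the list alone), with adjusted p = 1.4e-06, or adjusted p = 0.0936 with an estimated correlation. The TGF-beta list (3 of 14 higher, 4 adjusted over the list alone) and the YAP targets (3 of 14, 7 adjusted over the list alone, Ankrd1 at 1.39) passed at adjusted p = 2.5e-05 and adjusted p = 8.2e-05, both with adjusted p = 0.0557 with an estimated correlation. Of 18 matrix protease and inhibitor genes 4 rose and 1 fell (6 and 1 adjusted over the list alone), with the protease gene Ctss at 1.32, the inhibitor gene Timp1 at 1.22 and Timp4 at -0.55, and adjusted p = 1.8e-04, or adjusted p = 0.122 with an estimated correlation. The brown fat list was lower at a median of -0.40, with 0 of 12 genes past the limma threshold (3 lower adjusted over the list alone) and adjusted p = 1.0e-05, or adjusted p = 0.122 with an estimated correlation. Elastic fibre, basement membrane, cell cycle and interferon response were higher by camera and Hox lower, with adjusted p values from 0.0015 to 0.0162 and between 0.122 and 0.447 with an estimated correlation. The other 14 lists had adjusted p values from 0.0531 to 0.884. Of 24 other settings, Hspa5 lost its call in 11, Timp4 in 9, Calr in 4, and Asns and Ankrd1 in 2.

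For the mean Efemp2 KO contrast limma gave 584 genes, 482 higher and 102 lower. The count was 549 after cyclic loess (341 higher, 208 lower), 373 with the array background as a covariate (241 and 132), 664 without the 4 high-background arrays (397 and 267), 196 in a fit of the Efemp2 arrays alone and 366 to 860 with 1 array left out.

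In Lox KO aorta, the largest rises besides Col8a1, Igfbp2, Thbs1, Col11a1 and Gna14 (1.22 ± 0.15) were Ptgs2 (1.55 ± 0.23), the matricellular gene Ccn5 (1.28 ± 0.16), the monocyte chemokine genes Ccl2 (1.25 ± 0.21) and Ccl7 (1.24 ± 0.23), and the immediate early gene Egr1 (1.20 ± 0.22). Apart from Lox, the largest falls were Clca3a2, Cdr1 (-1.20 ± 0.24), Fmo4 (-1.07 ± 0.16), Pi15, Gabrb2, Bche, Angptl4, an inhibitor of lipoprotein lipase (-0.97 ± 0.16), A4galt (-0.92 ± 0.14) and the lipid droplet gene Cidea (-0.89 ± 0.23). Each of these 20 genes had the same sign in 4 of 4 pairs, with adjusted p values of at most 0.0345. Cidea lost its call after cyclic loess normalization and without any 1 of 12 arrays.

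Of 18 immediate early genes 6 rose in Lox KO (11 adjusted over the list alone), among them Egr1, Ier3 (0.98) and Nr4a1 (0.89), at a median of 0.34 and adjusted p = 3.9e-16, or adjusted p = 0.0116 with an estimated correlation. Of 15 macrophage genes 2 rose, Adgre1 (0.51) and Cx3cr1 (0.49), with 9 adjusted over the list alone, at a median of 0.44 and adjusted p = 4.7e-13, or adjusted p = 0.023 with an estimated correlation. List medians of single pairs are given here less the median shift of all tested genes. In AA P1 the platelet and erythroid medians, 0.67 and 0.62, were above the macrophage median of 0.42. In the other pairs they lay between -0.23 and 0.29 and the macrophage median between 0.32 and 0.51. Blood in the samples was not tested as a source of this rise. Of 14 YAP targets 2 rose (5 adjusted over the list alone), with adjusted p = 3.6e-08, or adjusted p = 0.0116 with an estimated correlation. In the hypoxia and glycolysis list 1 of 12 rose (3 adjusted over the list alone), with adjusted p = 3.5e-05, or adjusted p = 0.023 with an estimated correlation. The unfolded protein list passed upward (adjusted p = 0.00775, or adjusted p = 0.0319 with an estimated correlation) at a median of -0.01 and a mean of 0.04, with 0 of 14 genes past the limma threshold in either direction (0 adjusted over the list alone). Camera sets a list against the other genes, whose median was -0.09 in Lox KO. Of 22 collagen genes 6 rose (6 adjusted over the list alone), with adjusted p = 8.0e-11, or adjusted p = 0.0548 with an estimated correlation. Of 12 brown fat genes 2 fell (9 adjusted over the list alone) at a median of -0.58 and adjusted p = 4.6e-06, or adjusted p = 0.122 with an estimated correlation. Of 11 fatty acid oxidation genes 2, Angptl4 and Pdk4 (-0.59), fell (3 adjusted over the list alone), with adjusted p = 5.1e-04, or adjusted p = 0.213 with an estimated correlation. In the circadian clock list Npas2 fell by 0.55 (4 lower adjusted over the list alone), with adjusted p = 0.00625, or adjusted p = 0.175 with an estimated correlation. The interferon response (median 0.30, adjusted p = 6.1e-07, or adjusted p = 0.0561 with an estimated correlation) and TGF-beta lists (median 0.15, adjusted p = 3.4e-05, or adjusted p = 0.0548 with an estimated correlation) were higher by camera. The smooth muscle contractile, cell cycle, platelet, erythroid and heart muscle lists were higher and the endothelial list lower, with adjusted p values from 3.1e-05 to 0.0406 and from 0.109 to 0.576 with an estimated correlation. Among the 15 lists that did not pass, adjusted p ran from 0.0614 to 0.947, and 7 of them had a median or mean opposite in sign to the camera direction. Of 24 other settings, Pdk4 lost its call in 17, Cx3cr1 in 14 and Adgre1 in 3.

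For the mean Lox KO contrast limma gave 240 genes, 86 higher and 154 lower. After cyclic loess over all arrays it gave 209, 137 higher and 72 lower, and a fit of the Lox arrays alone gave 767. The count was 333 with the array background as a covariate (65 and 268), 443 without the 4 high-background arrays (123 and 320) and 127 to 301 with 1 array left out. No shared lowest values place the Lox P1 arrays in 1 normalization run. Their medians over all probe sets were 4.85 to 5.19 in KO and 5.21 to 5.35 in WT, which bears on the excess of lower genes.

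**Figure D3:**
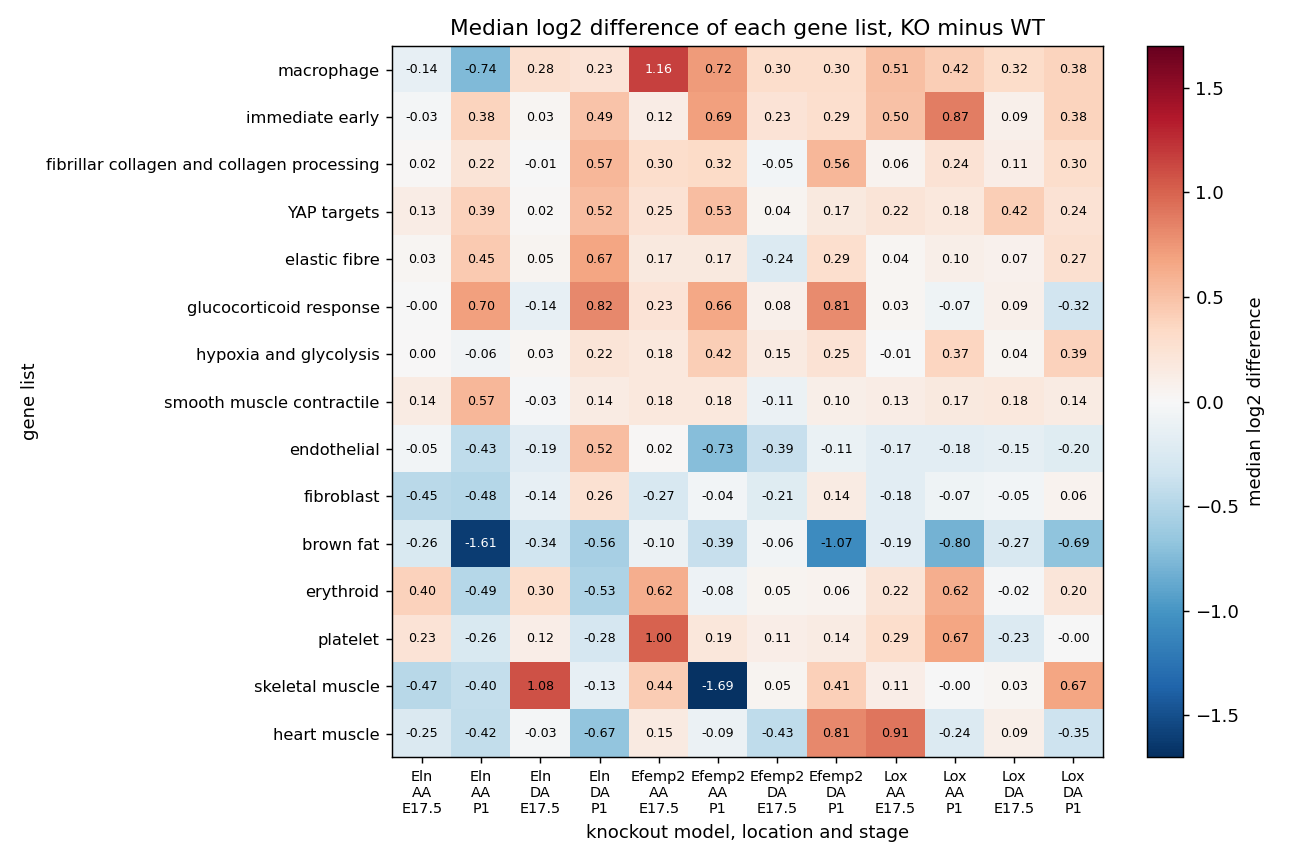
Median log2 difference, KO less WT, of 15 gene lists (vertical axis) in the 12 combinations of model, location and stage (horizontal axis), with red higher and blue lower and each value printed. From each value the median difference of all tested genes in that combination has been taken off. The macrophage list has its highest median in Efemp2 KO AA E17.5 at 1.16, and the brown fat list is below 0 in every column, down to -1.61 in Eln KO AA P1.

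The differences between the KO effects of the models were tested directly. Between Eln KO and Efemp2 KO, the effect in Eln KO was lower by 2.51 ± 0.42 for Serpina3n, 1.99 ± 0.41 for Saa3 and 1.76 ± 0.29 for Hmox1 (adjusted p = 0.00237, 0.0158 and 0.00194). The effect in Eln KO was higher by 1.67 ± 0.36 for Chad, 1.51 ± 0.21 for Moxd1, 1.28 ± 0.27 for Hapln1 and 1.16 ± 0.24 for Crabp2, of which Chad and Hapln1 lost their calls in 2 and Crabp2 in 1 of 40 other settings. In all, 85 genes differed between these effects, 30 higher and 55 lower in Eln KO. The count was 27 with only the arrays of the comparison, 51 with a random replicate block, 123 after cyclic loess and 45 to 146 with 1 array left out. Between Eln KO and Lox KO 78 genes differed, 74 higher in Eln KO, beside a median shift of all tested genes of 0.14, and after cyclic loess 14 did, 8 higher and 6 lower. Less that shift, the differences were 1.61 for Chad, 1.34 for Moxd1, 1.24 for Hapln1, -1.12 for Cxcl13 and -0.91 for the macrophage gene Adgre1. Of 40 other settings, Cxcl13 lost its call in 26, Chad in 4, Adgre1 in 2 and Hapln1 in 1. Between Efemp2 KO and Lox KO 4 genes differed, with a median shift of 0.13. Less that shift, these were Lox itself (3.03), Xdh (1.19), the glucocorticoid target Fkbp5 (0.65) and Pik3ip1 (0.63). Fkbp5 lost its call in 6 and Pik3ip1 in 9 of 40 settings, both of them after cyclic loess, which left 2 genes. Without the 4 high-background arrays, where DA P1 drops out of this difference, 6 genes differed between Eln KO and Lox KO, and Chad, Hapln1, Adgre1 and Cxcl13 were not among them.

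Within single location and stage pairs, Col8a1 was among the 3 largest rises in 9 of the 12. At E17.5, Eln KO gave 19 genes in AA and 7 in DA, Efemp2 KO 94 and 6, and Lox KO 4 and 2. In the E17.5 pairs Itgbl1 rose by 1.91 in Eln KO AA, Crabp2 by 1.88 in Eln KO DA, the leukocyte receptor gene Lilrb4a by 3.26 in Efemp2 KO AA, Saa3 by 3.74 and Ccl2 by 2.67 in Efemp2 KO DA, and Hmox1 by 2.13 in Lox KO AA. At P1, Eln KO gave 278 genes in AA and 3912 in DA, Efemp2 KO 568 and 238, and Lox KO 93 and 40. In AA at P1 the fat cell gene Adig fell by 3.11 in Eln KO. Car3, an enzyme of muscle and fat cells, fell by 3.46 in Efemp2 KO AA P1, and the mechanically induced gene Ankrd1 rose by 2.83 there. Less the median shift, the skeletal muscle list had a median of -1.69 in Efemp2 KO AA P1. The brown fat list had a median of -1.61 in Eln KO AA P1. Whether the samples differed in muscle or fat tissue was not tested. The median shift of all tested genes was -0.20 in Lox KO AA P1 and -0.17 in Lox KO DA P1. Less that shift, the cytokine gene Il6 differed by 2.98 and the glycosyltransferase gene Galnt15 by -1.81 in AA, and Ccn5 by 2.13 and the surfactant gene Sftpc, a lung epithelial gene, by -4.42 in DA. In Efemp2 KO DA P1 the brown fat gene Ucp1 fell by 3.35. The count in Eln KO DA P1 stood beside a median shift of 0.27 and both of its WT arrays were high-background arrays. With the array background as a covariate, which separated the genotypes in this pair, it was 41, and after cyclic loess it was 1393. Less the shift, Igfbp2 differed by 2.57 and Tgoln1 by 2.23, and the testis-type genes Srsy and Astx5 by -6.22 and -5.85. Over the other settings of these pairs Adig and Il6 kept their calls in 12 of 12, and Igfbp2 and Tgoln1 in Eln KO DA P1 in 11 of 11. Ucp1 lost its call in 7 of 12, Itgbl1, Crabp2 and Hmox1 in 5, Saa3 in 4, Ccl2, Car3, Ankrd1 and Sftpc in 3, Galnt15 and Ccn5 in 2 and Lilrb4a in 1. Srsy and Astx5 lost theirs with the array background as a covariate. Leaving out 1 array of a pair moved its count by more than 1.5 times in all 12 pairs.

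**Figure D4:**
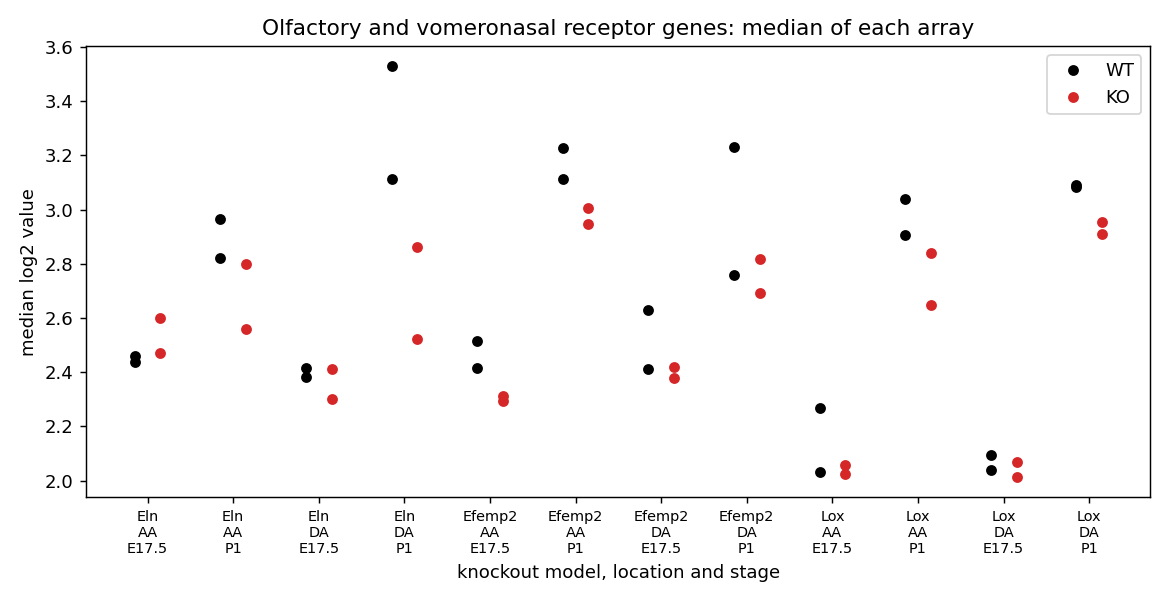
Median log2 signal of 1394 olfactory and vomeronasal receptor genes in each array (points), used as a measure of background, for the 12 combinations of model, location and stage, WT in black and KO in red. The Eln WT DA P1 arrays stand at 3.53 and 3.11, against 2.86 and 2.52 in Eln KO DA P1.

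Whether a KO effect differed by location or stage was tested as an interaction. Between DA and AA, 804 genes differed in Eln KO, 480 higher and 324 lower in DA, beside a median shift of 0.18. Less that shift, Emcn differed by 1.61, Adig by 1.65, Saa3 by 1.94 and the interferon-induced gene Isg15 by 1.62. Saa3 lost its call in 12 of 24 other settings and Isg15 in 3. After cyclic loess 248 genes differed, 72 higher and 176 lower in DA. With the array background as a covariate 21 genes differed. Without the 4 high-background arrays only the E17.5 pairs remain for this difference, where Adig stood at -0.16, so that fit does not test the 804 genes. In Efemp2 KO and in Lox KO limma found 0 genes whose effect differed by location, with 956 and 259 at an unadjusted p under 0.05. Between P1 and E17.5, 87 genes differed in Eln KO, 204 in Efemp2 KO and 15 in Lox KO, beside median shifts of 0.14, 0.10 and -0.20. Less these shifts, the stress gene Trp53inp1 differed by 1.49 and the glucocorticoid target Zbtb16 by 1.40 in Eln KO, and the mitochondrial hypoxia gene Ndufa4l2 differed by 1.84, Ccl2 by -1.83 and its receptor gene Ccr2 by -1.55 in Efemp2 KO. In Lox KO, the channel gene Trpm3 differed by -1.30, the cytokine receptor gene Il31ra by -1.26 and Galnt15 by -1.77. In the order Eln, Efemp2 and Lox KO, cyclic loess gave 2, 9 and 11 genes, a fixed replicate block 7, 3 and 2, the arrays of the model alone 64, 0 and 115, and the background covariate 1, 207 and 126. With 1 array left out the counts ran from 5 to 591, 8 to 841 and 4 to 98. Of the genes named for these interactions, Trpm3 alone kept its call under all alternatives and without any 1 array.

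In WT aorta, position genes were among the largest differences between DA and AA. The position genes Hoxb6, Hoxc6, Hoxa5 and Hoxa6 were higher in DA by 2.31 ± 0.14, 1.73 ± 0.14, 1.48 and 1.33. Dbh, a gene of catecholamine synthesis, was higher by 2.08 ± 0.31, and the secretory granule gene Chgb and the synaptic gene Snap25 by 1.82 ± 0.33 and 1.80 ± 0.29. The chemokine genes Ccl11 (1.92 ± 0.15) and Cxcl13 (1.63 ± 0.13), the lymphatic growth factor gene Vegfd (1.77 ± 0.12), the hedgehog-binding gene Hhip (1.71 ± 0.11) and Fads2b (1.83 ± 0.16) completed the 10 largest rises toward DA. Lower in DA were the transcription factor genes Osr2 (-2.20 ± 0.12) and Tcf21 (-2.01 ± 0.16), the growth factor gene Ptn (-1.62 ± 0.08), Flrt3 (-1.59 ± 0.14), Efemp1, which encodes fibulin-3 (-1.45 ± 0.14), and Sost, an inhibitor of Wnt signalling (-1.23 ± 0.15), with Reg3g, Cst9, Car8 and Defb2. All 20 had the same sign in 6 of 6 pairs, with adjusted p values of at most 0.0458. Reg3g, the weakest of them, lost its call under other settings.

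Of 21 Hox genes 15 were higher and 1 lower in DA (15 and 1 adjusted over the list alone), at a median of 0.57 and adjusted p = 8.6e-17, or adjusted p = 2.6e-05 with an estimated correlation. Hox was the only list of the 15 that passed both ways. Of 9 neuron and Schwann cell genes 6 were higher (6 adjusted over the list alone) at a median of 0.87 and adjusted p = 5.1e-07, or adjusted p = 0.106 with an estimated correlation. Of 17 endothelial genes 8 were higher (9 adjusted over the list alone), among them Vwf (0.95) and Kdr (0.88), with adjusted p = 5.1e-07, or adjusted p = 0.106 with an estimated correlation. Of 15 macrophage genes 5 were higher (8 adjusted over the list alone), with adjusted p = 2.7e-05, or adjusted p = 0.276 with an estimated correlation. Of 21 elastic fibre genes 7 were lower in DA (11 lower and 1 higher adjusted over the list alone), among them Efemp1, Fbn2 (-0.63) and Fbln1 (-0.51), with adjusted p = 6.4e-06, or adjusted p = 0.276 with an estimated correlation. Of 22 collagen genes 6 were higher (7 adjusted over the list alone), with Col8a1 at 1.51, and adjusted p = 0.00357, or adjusted p = 0.436 with an estimated correlation. Of 16 outflow tract transcription factor genes 5 were lower and 1 higher (5 and 1 adjusted over the list alone), among them Tbx20 (-1.12), Hand2 (-0.79) and Gata6 (-0.50), with adjusted p = 0.0339, or adjusted p = 0.336 with an estimated correlation. Of 10 thymocyte and lymphocyte genes 4 were lower and 1 higher (6 and 1 adjusted over the list alone), with the T cell receptor genes Cd3d (-1.14) and Cd3g (-1.10) lower, and adjusted p = 9.1e-04, or adjusted p = 0.276 with an estimated correlation. Brown fat, interferon response, fetal growth and vasoactive lists were higher in DA, and basement membrane, TGF-beta and cell cycle lists lower, with adjusted p values from 0.00234 to 0.0494 and from 0.276 to 0.53 with an estimated correlation. The other 17 lists had adjusted p values from 0.0544 to 0.993. In limma, 1318 genes differed, 711 higher and 607 lower in DA. The count without replicate 2 of Efemp2 WT AA P1 was 2224.

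Between stages the WT arrays differed as a whole, and no normalization set inferred from the values held both stages. The median shift of all tested genes from E17.5 to P1 was 0.48, and it was 0.01 in the Eln, -0.24 in the Efemp2 and 1.62 in the Lox model, so gene values are given less that shift. Among the genes furthest above it were Car3 at 3.45, the adipokine gene Adipoq at 3.42, the thermogenic gene Ucp1 at 2.96 and the mitochondrial gene Cox8b at 2.89. Adipoq stood 3.69, 3.13 and 3.48 above the shift of the Eln, Efemp2 and Lox models. The acute phase genes Saa3 and Serpina3n stood 2.43 and 2.42 above it, the mast cell protease gene Mcpt4 2.41, Fam107a 2.42 and the metallothionein gene Mt2 2.26. The embryonic globin gene Hba-x stood at -1.69, and the neural genes Fabp7, Stmn4 and Nefm stood at -1.74, -1.83 and -1.51. With the array background as a covariate these 4 genes lost their calls, as did Top2a, Pcna and Mcm6. In that fit Hba-x, Fabp7, Stmn4 and Nefm were at -0.30, 0.36, -0.25 and -0.18 before the shift was taken off, beside a median of all tested genes of 0.63. Of 24 cell cycle genes 12 were lower and 4 higher (12 and 4 adjusted over the list alone), with Top2a, Pcna and Mcm6 at -1.02, -1.01 and -1.07 less the shift, and at -0.99, -1.34 and -0.67 for Top2a in the separate models. The list's median was -0.70 less the shift, with adjusted p = 2.6e-12, or adjusted p = 0.125 with an estimated correlation. All 10 glucocorticoid response, all 12 brown fat, all 9 interferon response and all 15 macrophage genes were higher before the shift was taken off (10, 12, 9 and 15 adjusted over the list alone). These lists had adjusted p values of 4.4e-04, 8.4e-04, 0.00115 and 0.0152, and adjusted p = 0.227, 0.324, 0.324 and 0.464 with an estimated correlation. The fatty acid oxidation and thymocyte lists were higher and the unfolded protein, hypoxia, fetal growth, erythroid, heart muscle and neuron lists lower relative to other genes, at adjusted p values from 0.0152 to 0.0275 and from 0.125 to 0.62 with an estimated correlation. Of the 13 lists that passed, 6 had a positive median beside a downward test, and the other 19 had adjusted p values from 0.0702 to 0.95. In limma 11859 genes differed, 11175 higher and 684 lower. After cyclic loess 7962 genes differed, 4323 higher and 3639 lower.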

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

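The tests of cell type shares and blood in Efemp2 KO, the test of the receptor genes between stages, the array background as a covariate and the fit without the 4 high-background arrays were chosen only after the result was seen. The gene lists, the contrasts, the rule for naming genes and the other alternatives were set before the data were examined.

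Differences of KO effects between groups drew attention. The KO effect differed for 85 genes between Eln and Efemp2, for 78 between Eln and Lox and for 4 between Efemp2 and Lox. By location it differed for 804 genes in Eln KO, and by stage for 87 genes in Eln KO, 204 in Efemp2 KO and 15 in Lox KO. Each was tested as a difference of effects in limma.

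Other groupings of the same arrays were counted, with 100 splits per result including the real one. For Eln against Efemp2 1 split gave as many genes, the real one (highest other 21). The same held for Eln against Lox and for Efemp2 against Lox (highest other 1 in each). In the latter, Lox itself is among the 4 genes. The real grouping alone also reached the stage counts in Eln KO (highest other 3) and in Lox KO (highest other 0). These splits speak only to the main fit. After cyclic loess the stage counts were 2 and 11, and with a fixed replicate block 7 and 2. For the location difference in Eln KO 2 splits reached 804, with 915 as the highest other, and for the stage difference in Efemp2 KO 4 splits reached 204, with 517 as the highest other. In both, another grouping called more genes than the real one, so chance is not excluded for these counts. Splits that call more genes than the real grouping point to a structure of the samples. In Efemp2 KO and in Lox KO no gene differed by location in limma (956 and 259 at an unadjusted p under 0.05), so all 100 splits gave as many. There the highest other split called 703 genes in Efemp2 and 1 in Lox, and the 703 again point to a structure of the Efemp2 arrays.

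For the mean contrast of Lox KO 1 split reached 240, the real one, and the highest other gave 99. In Efemp2 KO 1 split reached 584, but another grouping called 574, so chance is not excluded for that count. In Eln KO 2 splits reached 504, and another grouping called 752, so chance is not excluded for that count. The high other splits in Eln and Efemp2 point to a structure of those arrays too. For genes changed in all 3 models 1 split reached 44, and the highest other gave 0. For WT DA against AA 1 split reached 1318 (highest other 1202). For WT P1 against E17.5, 10 splits reached 11859 and the highest other gave 13016, so chance could not be excluded by this count.

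Signals on probe sets outside the gene analysis also drew attention. Of 8838 tested probe sets without a gene name, 31 passed in Eln KO (22 higher, 9 lower), 19 in Efemp2 KO (15 higher, 4 lower) and 6 in Lox KO (5 higher, 1 lower). Of 1480 with several symbols, 5, 13 and 1 passed, with 3, 9 and 1 of them higher.

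The 3912 genes in Eln KO DA P1 were set against the raised background of both WT arrays. The difference of replicate 2 less replicate 1 of Efemp2 WT at P1, grouped by the signal on probe sets without a gene name (4.37 against 4.07 in AA, 4.36 against 4.09 in DA), shares no array with this pair. By the receptor genes the replicates differed less in AA (3.23 against 3.11) than in DA (3.23 against 2.76), so this test does not rest on that measure of background. The replicate difference correlated across genes with the Eln KO DA P1 difference at r = -0.5523, against -0.353 to 0.261 in the other 11 pairs; genes are not independent replicates. With the array background as a covariate 41 genes passed. Background separated the genotypes in this pair, at 3.53 and 3.11 in WT against 2.86 and 2.52 in KO. The covariate therefore cannot be told apart from genotype there and costs precision, so the fall to 41 does not decide the cause. After cyclic loess 1393 genes passed. The replicate correlation goes with raised background in the WT arrays as a source of part of the 3912. A biological difference between DA at P1 and the other pairs stays open as untested, since no low-background WT array of this pair exists among the 48.

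The macrophage markers in Efemp2 KO were set against a lower share of smooth muscle cells and against blood in the samples. A lower share would raise the markers of the other cell types alike, but the macrophage list rose by 0.9184 more than the endothelial list (SE 0.089), with means of 0.71 for macrophage, -0.21 for endothelial, -0.05 for fibroblast and 0.12 for smooth muscle contractile genes. Outside AA E17.5 the erythroid and platelet lists moved by 0.1518 (SE 0.093) and the macrophage list by 0.56 (SE 0.125), a difference of 0.41 (SE 0.131), which argues against blood as the whole cause there. In AA E17.5 they moved by 0.904 (SE 0.162) against 1.15 (SE 0.217), so blood could account for the rise in that pair, where replicate 1 of the WT also had little Eln signal. More macrophages, or more macrophage transcripts per cell, in the Efemp2 genotype stay open as untested biological explanations.

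The excess of higher genes in WT P1, 11175 of 11859, was set against an array-wide shift between sets. The median of the 1394 olfactory and vomeronasal receptor genes, which serve as a measure of background, rose by 0.6424, with 1221 higher and 13 lower, beside 0.48 for the tested genes. By model the receptor shift was 0.57, 0.50 and 0.89 in Eln, Efemp2 and Lox, and the shift of tested genes 0.01, -0.24 and 1.62, so the shift of tested genes did not follow the receptor genes. The values are consistent with a shift between sets as a source of the one-sided count, and stage and set cannot be told apart in the WT contrast. Development from E17.5 to P1 stays open as untested for the part beyond the shift.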

How the results depend on the processing

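The array background as a covariate and the fit without the 4 high-background arrays were chosen only after the data were seen, and the other alternatives were set before the data were examined. Counts are called moved where they differ by more than 1.5 times. Unless a reason is given, the cause was not tested.

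The count of genes changed in all 3 models stayed within that ratio under every alternative, at 34 to 49 against 44, and at 30 to 49 with any 1 of the 48 arrays left out. With the background covariate it was 38, 19 higher and 19 lower, and without the 4 high-background arrays 44, 27 higher and 17 lower. Of the 20 genes named for the mean contrast, 15 in Eln KO, 16 in Efemp2 KO and 19 in Lox KO kept their calls under all alternatives and without any 1 array. That held for 19 of 20 genes in WT DA against AA and for 8 of 18 in WT P1 against E17.5. Of the named list members past the threshold, 18 of 49 in Eln KO, 27 of 56 in Efemp2 KO, 16 of 27 in Lox KO, 57 of 76 in WT DA against AA and 74 of 122 in WT P1 against E17.5 kept their calls throughout. Of the genes named for differences of effects, 6 of 10 did between Eln and Efemp2, 3 of 8 between Eln and Lox and 2 of 4 between Efemp2 and Lox. By location 0 of 10 did in Eln KO, and by stage 0 of 10 in Eln KO, 0 of 10 in Efemp2 KO and 1 of 6 in Lox KO.

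Without the filter, which tests more genes, 8 counts moved. Efemp2 KO DA E17.5 gave 3 genes (6 with the filter), Lox KO AA E17.5 gave 2 (4), Lox KO AA P1 47 (93), the difference of Eln and Efemp2 52 (85), that of Eln and Lox 47 (78), the stage difference in Efemp2 KO 70 (204) and in Lox KO 6 (15), and WT P1 against E17.5 18148 (11859).

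After cyclic loess over all arrays, 10 counts moved. Eln KO DA P1 gave 1393 genes (3912), now 539 higher and 854 lower, Efemp2 KO AA P1 352 (568), DA E17.5 16 (6) and DA P1 98 (238), and Lox KO AA E17.5 7 (4). The difference of Eln and Lox gave 14, 8 higher and 6 lower (78), and that of Efemp2 and Lox 2 (4). The location difference in Eln KO gave 248, 72 higher and 176 lower (804), and the stage difference 2 in Eln KO (87) and 9 in Efemp2 KO (204). Loess removes the median shifts of these contrasts, so calls that rested on a shift end by construction. In WT P1 against E17.5, 8 named genes turned to negative values: Sesn2 (-0.047), Col9a1 (-0.086), Gata5 (-0.11), Hmga2 (-0.13), Uty (-0.16), Hemgn (-0.28), Ngfr (-0.30) and Rhag (-0.61). The loess took off the common shift, 0.48 before and 0.023 after it, so these turns restate that scaling. Less the shift, Hmga2, Uty, Hemgn, Ngfr and Rhag were already at -0.033, -0.084, -0.15, -0.19 and -0.42, and Sesn2, Col9a1 and Gata5 at 0.13, 0.064 and 0.023.

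With only the arrays of the comparison, 18 counts moved. Efemp2 KO gave 196 genes in the mean (584), 22 in AA E17.5 (94), 48 in AA P1 (568) and 14 in DA P1 (238). Lox KO gave 767 in the mean (240), 22 in AA E17.5 (4), 255 in AA P1 (93), 1 in DA E17.5 (2) and 94 in DA P1 (40). Eln KO gave 5 in AA E17.5 (19), 103 in AA P1 (278) and 1 in DA E17.5 (7). The difference of Eln and Efemp2 gave 27 (85), that of Eln and Lox 207 (78), the location difference in Lox KO 1 (0), the stage difference in Efemp2 KO 0 (204) and in Lox KO 115 (15), and WT DA against AA 845 (1318). With trend and robust variances 1 count moved, the stage difference in Lox KO, to 7 (15).

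The AA and DA arrays of the same model, genotype, stage and replicate number were tested as a block. The difference of replicate 1 less replicate 2 correlated across genotypes at r from -0.234 to 0.203 (above 0.1 in 3 of 12). Across locations r ran from -0.251 to 0.356 (3 of 12) and across stages from -0.295 to 0.218 (2 of 12). Genes are not independent replicates. These values show no general pairing by number, but they cannot exclude that AA and DA arrays of 1 number share aortas. In Lox KO at E17.5, Lox was higher in replicate 1 in both locations, at 7.99 against 6.56 and 7.93 against 6.26. The main fit treats such arrays as independent. As a fixed term the block moved 8 counts. Eln KO AA E17.5 gave 9 (19), Lox KO AA P1 39 (93) and DA P1 19 (40), the difference of Efemp2 and Lox 2 (4), the location difference in Eln KO 1398 (804), and the stage difference 7 in Eln KO (87), 3 in Efemp2 KO (204) and 2 in Lox KO (15). As a random term, with a correlation of 0.091, it moved 6: the difference of Eln and Efemp2 to 51 (85), that of Eln and Lox to 40 (78), the location difference in Eln KO to 1407 (804), and the stage differences in Eln, Efemp2 and Lox KO to 35, 31 and 6 (87, 204 and 15). With the random term the mean contrasts of Eln, Efemp2 and Lox KO gave 378, 456 and 172 genes (504, 584 and 240). Camera cannot take a random block, so that alternative was not run for lists.

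With the array background as a covariate, 12 counts moved. Eln KO gave 218 in the mean (504), 431 in AA P1 (278) and 41 in DA P1 (3912), Efemp2 KO 373 in the mean (584), 295 in AA P1 (568) and 77 in DA P1 (238), and Lox KO 234 in AA P1 (93) and 67 in DA P1 (40). The location difference in Eln KO gave 21 (804), the stage difference 1 in Eln KO (87) and 126 in Lox KO (15), and WT P1 against E17.5 6455 (11859). Turned in WT P1 against E17.5 were Fabp7 (0.36), Top2a (0.18), Tnnc1 (0.55), Mcm6 (0.040) and Tubb3 (0.65), and in Eln KO DA P1 Mpc1 (-0.087). The values in WT P1 stand beside a median of all tested genes of 0.63 in that fit, so their sign goes with a shift common to all genes, and all but Tubb3 stood below it. The means of 2 lists less that of the other genes turned in WT P1 against E17.5, to 0.44 for basement membrane and -0.10 for thymocyte and lymphocyte genes.

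Without the 4 high-background arrays, 17 counts moved, and Eln KO DA P1 has no value because no WT array of it remains. Eln KO gave 248 in the mean (504), 30 in AA E17.5 (19), 521 in AA P1 (278) and 12 in DA E17.5 (7). Efemp2 KO gave 1325 in AA P1 (568), 13 in DA E17.5 (6) and 96 in DA P1 (238). Lox KO gave 443 in the mean (240), 11 in AA E17.5 (4), 160 in AA P1 (93) and 66 in DA P1 (40). The difference of Eln and Lox gave 6 (78), that of Efemp2 and Lox 33 (4), the location difference 0 in Eln KO (804) and 17 in Efemp2 KO (0), and the stage difference 6 in Eln KO (87) and 60 in Lox KO (15). Without these arrays the mean of Eln KO and its differences from the other models rest on 3 pairs. The location difference in Eln KO rests on the E17.5 pairs alone and its stage difference on the AA pairs alone, so their counts are not of the same contrasts. In the location difference at E17.5, Adig stood at -0.16.

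With 1 array left out, the lone array of its group is assumed to vary like the other groups. Counts then ran as follows, lowest to highest. Eln KO gave 331 to 872 in the mean (highest without replicate 2 of the WT in DA P1), 4 to 8 in AA E17.5, 73 to 296 in AA P1, 1 to 3 in DA E17.5 and 2025 to 3807 in DA P1. Efemp2 KO gave 366 to 860 in the mean, 25 to 438 in AA E17.5 (highest without replicate 2 of the WT), 90 to 967 in AA P1, 0 to 1 in DA E17.5 and 43 to 1015 in DA P1. Lox KO gave 127 to 301 in the mean, 1 to 119 in AA E17.5 (highest without replicate 2 of the WT), 14 to 20 in AA P1, 0 to 2 in DA E17.5 and 2 to 26 in DA P1. The difference of Eln and Efemp2 ran from 45 to 146, of Eln and Lox from 24 to 137 and of Efemp2 and Lox from 2 to 16. The location difference ran from 82 to 1405 in Eln KO, 0 to 16 in Efemp2 KO and 0 to 1 in Lox KO, and the stage difference from 5 to 591, 8 to 841 and 4 to 98. WT DA against AA ran from 1010 to 2224 (highest without replicate 2 of Efemp2 WT AA P1) and WT P1 against E17.5 from 11511 to 11982.

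With an estimated correlation 66 of the list results no longer passed and 94 kept their side of the threshold. List calls were lost in 13 cases and gained in 8 after cyclic loess, in 8 and 15 with the background covariate, in 11 and 9 without the 4 high-background arrays, and in 2 and 16 without the filter. With 1 array left out they were lost in 81 cases and gained in 81. The lists that passed with it were 4 in Efemp2 KO, 5 in Lox KO, 1 in WT DA against AA and 0 in Eln KO and in WT P1 against E17.5. Signal over background limits what can be read from dim genes: the filter stood at 4.94, and the receptor genes, taken as background, reached a median of 3.53 in Eln WT DA P1.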

Other observations

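The sterol list was written after Fdps, Cyp51 and Insig1 had been seen among the changed genes, and its test on the other genes was planned before their values were looked at. Beyond the gene groups of the report, these 3 genes of sterol synthesis passed the limma threshold in all 3 models. Fdps, which makes farnesyl pyrophosphate, was higher by 0.64 in Eln KO, 0.59 in Efemp2 KO and 0.64 in Lox KO. The demethylase gene Cyp51 was higher by 0.49, 0.60 and 0.59, and Insig1, a sterol-sensing regulator, by 0.58, 0.45 and 0.57. These genes were chosen after their values were seen. Hmgcs1 and Sqle belong to the genes whose values had not been seen when the test was planned, and they are named here only after it was run. Hmgcs1, an early enzyme of the pathway, was higher by 0.64 in Lox KO (adjusted p = 0.0208) and 0.55 in Efemp2 KO (adjusted p = 0.0316) and did not pass in Eln KO (0.20, adjusted p = 0.579). Sqle passed in Lox KO alone, at 0.60 (adjusted p = 0.0182), with 0.44 in Eln KO and 0.46 in Efemp2 KO; whether these effects differ between models was not tested for it.

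The hypothesis was that the whole pathway, and not only the genes seen first, is higher in each model. Camera was run on the 15 other tested genes of the list. Their median was 0.22 in Eln KO with 14 of 15 above 0 and 2 past the limma threshold (p = 6.9e-04, or 0.0588 with an estimated correlation), 0.15 in Efemp2 KO with 12 of 15 and 2 past it (p = 0.00584, or 0.12) and 0.23 in Lox KO with 15 of 15 and 5 past it (p = 7.0e-14, or 2.0e-04). The test passed in 3 models, the number predicted, but with an estimated correlation in Lox KO alone, and most of the 15 genes did not pass singly. Relative to other genes, the 15 genes were therefore higher as a set in Lox KO, and the evidence for the other models rests on the preset correlation. The median of all tested genes was 0.055 in Eln KO and -0.088 in Lox KO, beside list medians of 0.22 and 0.23. Camera sets a list against the other genes, so its smaller p in Lox KO does not show a larger rise there. The first 3 genes were seen in these same arrays, so the test is not independent of them. The cell type in which these transcripts are higher was not tested.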
